A study of Mus musculus with 20 samples.

How the data were processed

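RNA from 20 mouse samples was measured on Affymetrix Mouse Genome 430 2.0 arrays, 1 array per sample. Per the labels' protocols, tissues were frozen and homogenized, and biotin-labelled cRNA was made from 40 ng of total RNA by 2 cycles of amplification. The deposited values are probe set intensities on a linear scale. The mean of each array after trimming 2% at each end was 100, which shows that the authors had scaled the arrays to each other. The software that summarized the probes is not given in the sources used here, and no detection calls were used.

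The deposited intensity values were transformed here to log2(intensity + 16) and not normalized again, because the array medians on that scale spanned 0.33, under the 0.5 set beforehand. A fold change on this scale understates the change of genes of low intensity. Of 45101 probe sets, 64 control probe sets were left out. Of the remaining 45037, the platform annotation listed 1 gene symbol for 34945, several symbols for 932 and was silent on 9160, which are unnamed here. Symbols were updated through the gene identifiers of a mouse gene table (assembly GRCm38.p6), which held 34741 of the 34945; the other 204 kept the symbol of the annotation. No coordinates are given. Each gene was represented by its probe set with the highest mean over the 20 arrays, which gave 18193 genes. A gene was tested if it was above the 40th percentile of its array on at least 2 arrays, which left 15132 genes.

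The groups were taken from the titles: 4 ganglion samples of wild-type mice, 2 ganglion samples of mice homozygous for the MYCN transgene, 4 tumors of homozygous mice, 2 tumors of homozygous mice with a knockout of Mdk, 4 tumors of hemizygous mice, 2 neurosphere cultures of wild-type mice and 2 tumorsphere cultures of hemizygous mice. The labels do not say whether samples of a group came from separate animals or cultures, so the p-values measure the spread between these samples, which may be partly technical. The number of arrays limits the precision of every value.

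All 20 arrays were fitted in 1 linear model with 7 group means (limma 3.58.1 in R 4.3.3, lmFit and eBayes, 13 residual degrees of freedom before moderation). Each comparison is a contrast of that model, two-sided, with Benjamini-Hochberg adjustment over the 15132 genes and a threshold of 0.05. The model assumes that a gene has the same spread in all groups, which may not hold. With only the compared arrays, counts of changed genes moved both ways. They went from 758 to 144 for homozygous against wild-type ganglia and from 3271 to 6291 for homozygous tumors against homozygous ganglia. Every adjusted p of a gene in the text is from limma. In total 24 gene lists were fixed before the data were examined, and 23 of them were tested with limma's camera at its preset inter-gene correlation of 0.01, with adjustment over the lists of a comparison. The remaining list, sex-linked genes, was used for values per array. Camera with a correlation estimated from the data was run as an alternative, and its p is given beside the lists. List members are also counted with p adjusted over the list alone.

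Named genes follow a rule fixed before the data were examined. For each of 6 main comparisons these are the 6 genes with the highest and the 6 with the lowest log2 fold change among those that passed and whose groups did not overlap, without clone names and sex-linked genes. Where fewer than 6 passed, up to 3 with the smallest unadjusted p stand in and are said not to pass. Further comparisons take 4 and 4. The 3 members with the smallest p of each list that passed, and Mdk, Mycn, Notch2, Hes1, Ptprz1 and Alk, are added. The text names part of this set. Named genes were not followed in the term for replicates 1 and 2 against 3 and 4, the 2-fold threshold and the alternatives added after seeing the data. For 37 of the 215 named genes the probe set can match several transcripts by its name.

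The sequences of the probes and the position of the probe sets in their genes were not analysed here. The steps were tested on simulated arrays with the measured gene means and spreads and 100 genes changed by each of 2 sizes among 15132. For homozygous tumors against wild-type ganglia, 66% of genes changed by 1 log2 unit and 98% of those changed by 2 were recovered, and 6.29% of the genes called were false. For homozygous against wild-type ganglia the shares recovered were 46% and 94%, with 8.5% of the called genes false, the highest of the 6 main comparisons. The shares recovered were 40% and 98% for tumors with Mdk knockout against homozygous tumors and 30% and 88% for tumorspheres against neurospheres. The simulated values varied independently, with 1 spread per gene for all groups and without differences between arrays of a group such as those among wild-type ganglia. These shares test the steps and are not error rates of the measured results.

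Alternatives were quantile normalization, median centring, pseudocounts of 1 and 64, no filter, a 60th percentile filter, the mean of a gene's probe sets, probe sets without the _x_at and _s_at kinds, a variance trend, array weights, only the compared arrays, the replicate number as a block, a term for replicates 1 and 2 against 3 and 4, an added 2-fold threshold, and each array left out in turn. Added after seeing the data were only wild-type ganglia 1 and 2, only 3 and 4, leaving out 6 arrays with Acta1 intensity over 100, and a term for sex. The correlation of the deviations of samples with the same replicate number was over 0.1 in 3 of the 12 pairs among the groups of 4. All 3 were among the 4 pairs of wild-type ganglia with homozygous tumors (0.0711, 0.254, 0.206 and 0.139), and the 8 pairs with hemizygous tumors were negative, so the numbers were not treated as pairing.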

Results

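The arrays compared tumors, ganglia and sphere cultures of mice carrying a MYCN transgene with ganglia and neurospheres of wild-type mice. MYCN is a transcription factor whose gene is amplified in aggressive neuroblastoma, a tumor of the sympathetic nervous system, and mice that carry the transgene develop such tumors. Mdk encodes midkine, a heparin-binding growth factor, and part of the tumors came from mice without a functional Mdk gene. The 20 arrays comprised 4 wild-type ganglion samples, 2 homozygous ganglion samples, 4 homozygous tumors, 2 homozygous tumors with Mdk knockout, 4 hemizygous tumors, 2 wild-type neurosphere cultures and 2 hemizygous tumorsphere cultures. The highest correlation between 2 arrays was 0.99, and identical intensities made up at most 0.0022% of the probe sets of any pair, so no array was counted as a repeat of another. The 3' to 5' ratio of the beta-actin control was 6.88 ± 2 (SD, n = 4) in wild-type ganglia, 2.55 ± 0.17 (SD, n = 4) in homozygous tumors and 2.2 ± 0.34 (SD, n = 4) in hemizygous tumors. It was 4.35 ± 0.47 (SD, n = 2) in homozygous ganglia, 5.78 ± 2.8 (SD, n = 2) in neurospheres and 2.49 ± 0.21 (SD, n = 2) in tumorspheres. The ratio of the GAPDH control was 3.37 and 11.5 in the neurospheres and 3.13 and 2.68 in the tumorspheres. Wild-type ganglia 1 and 2 differed from 3 and 4. Acta1, the actin of skeletal muscle, read 1040 and 529 in the former and 16 and 7.1 in the latter, Xist, which is expressed in females, 2410 and 2480 against 44 and 30.7, and Notch2 169 and 195 against 924 and 911.

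The targeted gene was examined first. Mdk intensity was 42.6 and 35.5 in the tumors labelled as Mdk knockout and 277 ± 13.9 (SD, n = 4) in homozygous tumors. Where the probe set lies relative to the deleted part of Mdk is not known here. Mdk was 70.1 ± 25.8 (SD, n = 4) in wild-type ganglia, 197 ± 15 (SD, n = 2) in homozygous ganglia, 340 ± 108 (SD, n = 4) in hemizygous tumors, 43.3 ± 14.6 (SD, n = 2) in neurospheres and 400 ± 90.5 (SD, n = 2) in tumorspheres. The brighter mouse Mycn probe set read 319 ± 72.9 (SD, n = 4) in wild-type ganglia, 144 ± 21.8 (SD, n = 4) in homozygous tumors and 39.1 ± 28.6 (SD, n = 4) in hemizygous tumors. A second, dimmer Mycn probe set went the other way, with 8.92 ± 5.07 (SD, n = 4) in wild-type ganglia, 44.5 ± 18.8 (SD, n = 4) in homozygous tumors and 55.2 ± 21.3 (SD, n = 4) in hemizygous tumors. Another Mycn probe set, with a mean of 16.8 over all arrays, was at log2 -0.63 in homozygous and -0.51 in hemizygous tumors against wild-type ganglia. The transgene may not be read by the mouse probe sets, so none is taken as its level.

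**Figure D1:**
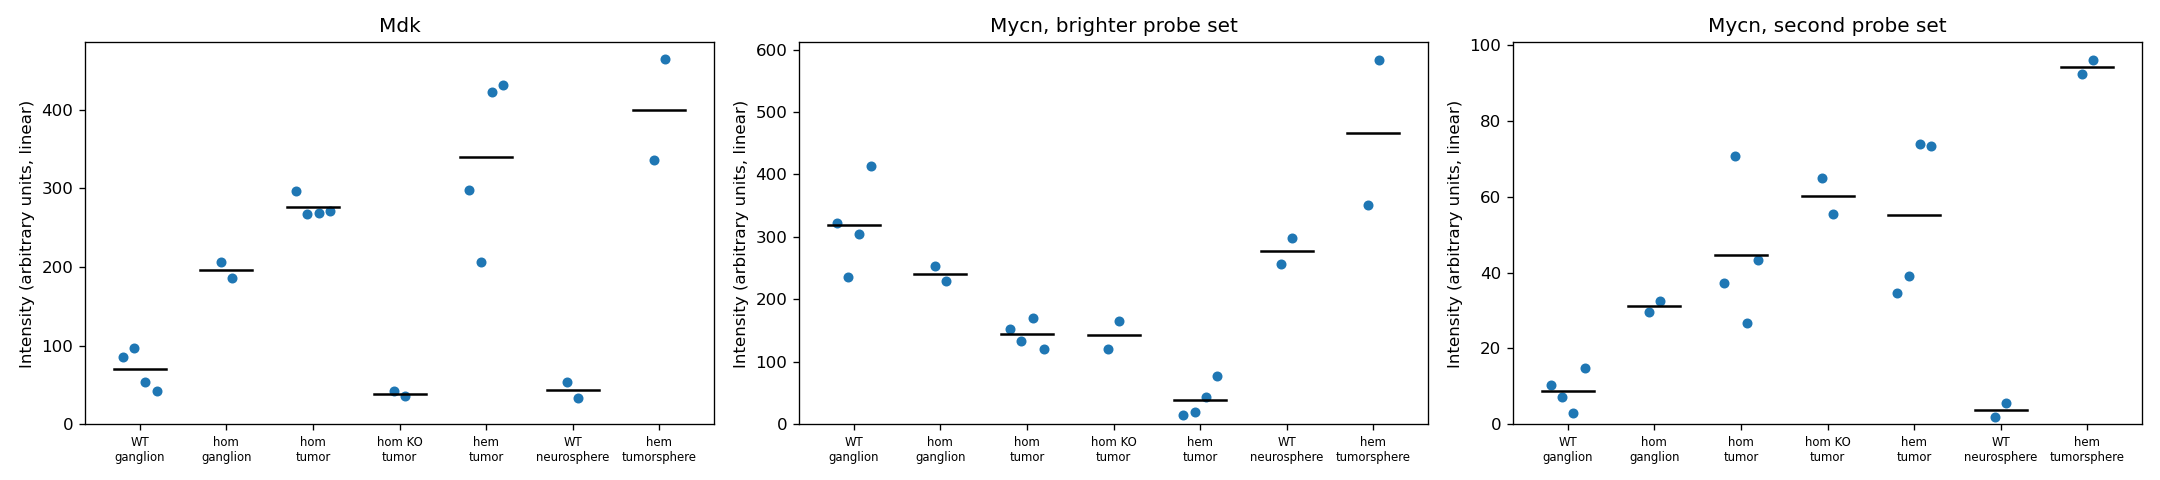
Intensity of Mdk and of the brighter and the second Mycn probe set on each array (points) by group, with the group mean as a line, on linear axes. Mdk was 42.6 and 35.5 in the knockout tumors (hom KO) against 268 to 297 in the 4 homozygous tumors.

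Homozygous tumors were set against wild-type ganglia to find how tumor tissue differs from the normal tissue. Cell division genes were higher in the tumors: all 39 tested members of the cell cycle list rose (also 39 adjusted over the list alone), with a median log2 fold change of 3.24 (adjusted p = 0.07 with an estimated correlation). Top2a, which untangles replicating DNA, was 1950 ± 73.6 (SD, n = 4) against 79.1 ± 45.5 (SD, n = 4), and Cdc20, an activator of the anaphase-promoting complex, was 2390 ± 186 against 116 ± 47.7. In the differentiated neuron list 16 of 27 fell and 2 rose, and in the Schwann and satellite glia list 14 of 19 fell and 1 rose (adjusted p = 0.18 each with an estimated correlation). Npy, a neuropeptide of sympathetic neurons, was 79 ± 39.1 in tumors and 3710 ± 491 in ganglia, and the glial gene Fabp7 was 339 ± 55.9 against 4730 ± 471. The tumors also had more Insm1, a transcription factor of neuroendocrine precursors, at 1130 ± 337 against 5.04 ± 3.64.

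Of 15132 genes, 7533 changed between homozygous tumors and wild-type ganglia, 3503 higher and 4030 lower, although the 60th percentile filter gave 3437 higher and 3427 lower. Of the 7533, 5958 also passed with wild-type ganglia 1 and 2 alone and 6429 with 3 and 4 alone, settings chosen after seeing the data. The beta-actin 3' to 5' ratio was 6.88 in wild-type ganglia and 2.55 in these tumors, so RNA quality cannot be separated from tissue here. The GAPDH ratio differed less, with 3.42 ± 0.68 (SD, n = 4) in wild-type ganglia and 3.07 ± 0.38 (SD, n = 4) in these tumors. The highest fold changes after Insm1 (log2 5.73, SE 0.2, adjusted p = 2.5e-12) belonged to Agtr2, Dlk1, Meis2 and Tox3, with log2 changes of 5.09, 4.96, 4.67 and 4.66. The lowest belonged to Npy (-5.37), Prr15 (-5.27), Tspan8 (-5.24), Olfr78 (-4.75), Hbb-b2 (-4.54) and Sncg (-4.47). The median of all tested genes was -0.12 in this contrast, so small changes have to be read against that value. Hbb-b2 is a globin gene, read here by a probe set that can match several transcripts. Another Hbb-b2 probe set, with a mean of 20.7 over all arrays, was at -0.54. Alas2, an enzyme of heme synthesis in red cells, fell by 4.22. In the erythroid list 4 of 6 genes fell (list adjusted p = 0.049, 0.47 with an estimated correlation).

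In the ribosome biogenesis and MYC target list, 38 of 42 members rose and 1 fell (median 1.35, adjusted p = 2.3e-12, and 0.18 with an estimated correlation). Nop58, a component of the small nucleolar ribonucleoproteins, was 387 ± 48.3 against 76.9 ± 13.7 (SD, n = 4 each). In the Polycomb group, 12 of 25 rose and 2 fell, or 13 and 3 adjusted over the list alone (adjusted p = 0.0022, and 0.07 with an estimated correlation), led by Ezh2, the histone methyltransferase, at 1170 ± 100 against 135 ± 18.1. In the differentiated neuron list 16 of 27 fell and 2 rose (adjusted p = 0.00039, and 0.18 with an estimated correlation). In the Schwann and satellite glia list 14 of 19 fell and 1 rose (0.00025, and an adjusted p of 0.18 with an estimated correlation), with Mal and Pmp22, both myelin proteins, at log2 -4.02 and -3.17. In the fibroblast and extracellular matrix list 22 of 29 fell and 1 rose, with 23 fallen adjusted over the list alone (1.8e-05, and an adjusted p of 0.41 with an estimated correlation), although Fbln1 rose by 2.69. In the neural crest and neural stem list 15 of 26 fell, 16 adjusted over the list alone, and 3 rose (0.0058, and an adjusted p of 0.18 with an estimated correlation), among them Prom1 (-3.19) and Sox2 (-2.25). In the antigen presentation and interferon list 17 of 22 fell, and 18 adjusted over the list alone (6.2e-05, and an adjusted p of 0.26 with an estimated correlation), with B2m, the light chain of class I molecules, at 309 ± 52.2 against 2130 ± 257. The cell cycle list had an adjusted p of 2.9e-29, and 0.07 with an estimated correlation. Among the study genes Mdk (log2 1.81, SE 0.23) and Alk, a receptor tyrosine kinase mutated in neuroblastoma (2.62, SE 0.23), rose, Ptprz1, a midkine receptor, fell by 2 (SE 0.27), and Hes1 did not pass (log2 -0.76, adjusted p = 0.12). Notch2 (-1.99) and Mycn by its brighter probe set (-1.05) also passed downward, while the second Mycn probe set was at 1.25. Notch2 ranged from 169 to 924 in the wild-type ganglia. The midkine, pleiotrophin and receptor list, in which 5 of 18 rose and 8 fell, did not pass (adjusted p = 0.52). Acta1 was over 100 on 6 arrays, which were wild-type ganglia 1 and 2, homozygous ganglion 2, homozygous tumor 2, knockout tumor 2 and hemizygous tumor 3, and the skeletal muscle list did not pass here (median -1.36, adjusted p = 0.16).

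**Figure D2:**
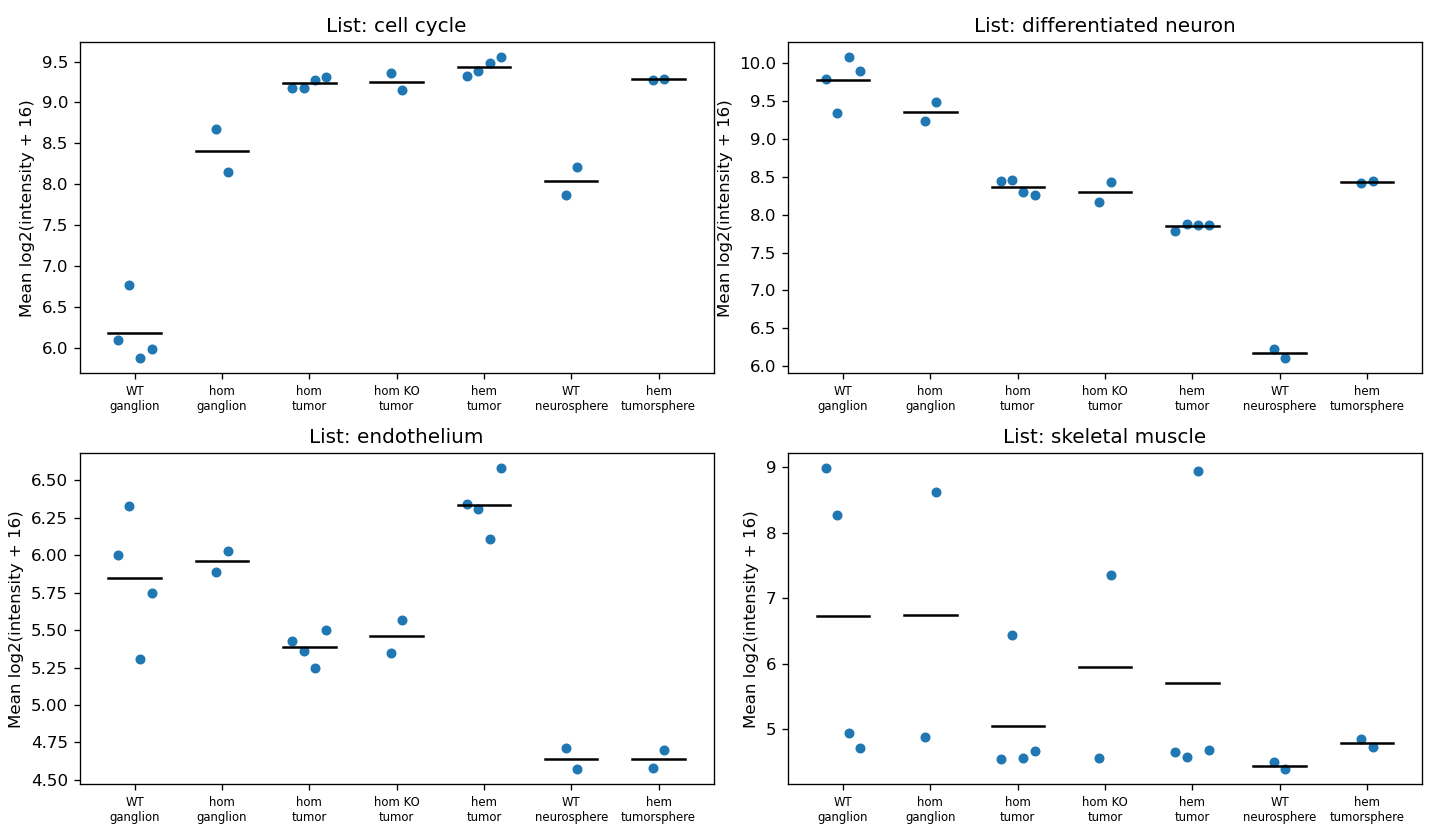
Mean log2(intensity + 16) over the genes of 4 lists on each array (points) with the group mean (line). The cell cycle list is lowest in wild-type ganglia, and the skeletal muscle list is high on single arrays of several groups.

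Hemizygous tumors were set against the same wild-type ganglia. All 39 cell cycle genes rose, 19 of 27 neuron genes fell and 3 rose, and 13 of 19 glial genes fell and 1 rose (adjusted p = 0.089, 0.089 and 0.11 with an estimated correlation). Insm1 was 1020 ± 146 (SD, n = 4) against 5.04 ± 3.64 (SD, n = 4), and Dlk1, an imprinted Notch family ligand, 1860 ± 173 against 39 ± 25.3. Fabp7 was 25.8 ± 25 against 4730 ± 471, and Slc6a2, the noradrenaline transporter, 136 ± 202 against 6480 ± 2810. In the macrophage and myeloid list 13 of 21 rose and 2 fell (adjusted p = 0.005, and 0.54 with an estimated correlation), including Cd68, a lysosomal protein of macrophages, at 281 ± 117 against 19.4 ± 6.77. The mean of that list was 6.74 in hemizygous tumor 3 and 7.36 to 7.99 in the others. The difference from homozygous tumors is tested in its own comparison.

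Of 15132 genes, 7958 changed, 4086 higher and 3872 lower, or 3802 higher and 4036 lower after quantile normalization. Of the 7958, 6412 also passed with wild-type ganglia 1 and 2 alone and 6942 with 3 and 4 alone, settings chosen after seeing the data. With a beta-actin ratio of 6.88 in wild-type ganglia and 2.2 in these tumors, RNA quality cannot be separated from tissue in this contrast either. The GAPDH ratio differed less, with 3.42 ± 0.68 (SD, n = 4) in the ganglia and 2.94 ± 0.19 (SD, n = 4) in these tumors. The highest were Insm1 (log2 5.63), St18 (5.33), Dlk1 (5.21), Agtr2 (5.03), Bub1b (4.94) and Tox3 (4.83), and the lowest Fabp7 (-7.01), Slc6a2 (-6.3), Prph (-6.21), Prr15 (-6.17), Tspan8 (-6.13) and Sncg (-5.99). All 39 cell cycle genes rose (median 3.39, adjusted p = 6.3e-26, and 0.089 with an estimated correlation). Of the ribosome biogenesis list 41 of 42 rose and 1 fell (median 1.93, adjusted p = 6.6e-15, and 0.13 with an estimated correlation), and of the Polycomb group 15 of 25 rose and 3 fell (0.0019, and an adjusted p of 0.089 with an estimated correlation). Of the neuron list 19 of 27 fell (median -1.85, adjusted p = 1.9e-06, and 0.089 with an estimated correlation) and of the glial list 13 of 19 (7.3e-05, and an adjusted p of 0.11 with an estimated correlation). Of the sympathetic noradrenergic list 13 of 22 fell and 4 rose (0.027, and an adjusted p of 0.49 with an estimated correlation), with Dbh, which makes noradrenaline, at 159 ± 73.8 against 2210 ± 722. In the sterol biosynthesis list 9 of 19 fell and 1 rose (0.027, and an adjusted p of 0.42 with an estimated correlation), with Fdft1, squalene synthase, at 504 ± 21.9 against 2660 ± 520. The fibroblast (0.00073, estimated-correlation adjusted p of 0.51), erythroid (0.045 and 0.49), neural crest (0.031 and 0.37) and antigen presentation (0.046 and 0.62) lists also went down at the preset correlation. Mdk rose (log2 2.04, SE 0.23) and Alk rose (1.67, SE 0.23), while Notch2 fell by 1.58 with wild-type ganglia spread from 169 to 924.

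Ganglia of homozygous mice were set against wild-type ganglia, which asks whether tissue that carries the transgene but is not labelled as tumor already differs. Cell cycle genes were higher: 36 of 39 rose and none fell (37 adjusted over the list alone), with a median log2 fold change of 2.27. Rrm2, a subunit of ribonucleotide reductase, was 1830 ± 546 (SD, n = 2) against 133 ± 68.8 (SD, n = 4), and Melk 432 ± 140 against 59.9 ± 15.4. Insm1 was 622 ± 139 against 5.04 ± 3.64 and Agtr2, the type 2 angiotensin receptor, 1500 ± 444 against 68.3 ± 38.1. Mdk and Alk rose by 1.35 (SE 0.29, adjusted p = 0.0079) and 1.37 (SE 0.28, adjusted p = 0.0066), but neither passed without homozygous ganglion 1 (log2 1.28, adjusted p = 0.17 for Mdk and 1.21, adjusted p = 0.2 for Alk).

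Here 758 genes changed, 604 higher and 154 lower. Egln3, a prolyl hydroxylase of the hypoxia response, Nfe2l3 and Sytl4 rose by 3.83, 3.66 and 3.61, and Plcl1, Sntb1, Tmem179, Ralyl, Kcnab1 and Grm7 were the lowest, between -2.16 and -1.67. Without homozygous ganglion 1, Plcl1, Sntb1, Tmem179, Ralyl and Grm7 were at -2.06, -2.17, -1.57, -1.51 and -1.53 and did not pass (adjusted p = 0.3, 0.24, 0.39, 0.25 and 0.43). The cell cycle list passed both with the preset (adjusted p = 1.1e-55) and with an estimated correlation (adjusted p = 0.012). In the ribosome biogenesis list 6 of 42 rose and none fell, and 14 rose adjusted over the list alone (adjusted p = 3e-10, and 0.44 with an estimated correlation), with Fbl at 482 ± 86.2 against 133 ± 82.4. In the Polycomb group 5 of 25 rose and 1 fell (0.026, and an adjusted p of 0.28 with an estimated correlation), with Ezh2 at 525 ± 100 against 135 ± 18.1. In the glial list 3 of 19 fell, and 5 adjusted over the list alone (0.02, and an adjusted p of 0.46 with an estimated correlation). No member passed alone in the neuron (list adjusted p = 0.019, and 0.46 with an estimated correlation), macrophage (0.022 and 0.67) and antigen presentation (0.019 and 0.62) lists, and 1 of 24 immediate early genes fell, and 4 adjusted over the list alone (0.037 and 0.44). The sympathetic list did not pass (adjusted p = 0.66), and the skeletal muscle list neither (0.94). The count depended on which wild-type ganglia were used: 515 with ganglia 1 and 2 alone (470 higher, 45 lower) and 5283 with ganglia 3 and 4 alone (2865 higher, 2418 lower), the latter holding 751 of the 758. Fitting only the compared arrays gave 144, all higher. It was 1177 without wild-type ganglion 1, 2232 without wild-type ganglion 2 (1222 higher, 1010 lower), 189 without homozygous ganglion 1 and 370 without homozygous ganglion 2, and 3079 without the 6 arrays with Acta1 over 100 (1675 higher, 1404 lower). The homozygous ganglia read 2710 and 2540 for Xist, 1210 and 1610 for Adipoq, a fat cell gene, 426 and 440 for Alb and 509 and 573 for Ttr. Wild-type ganglia 1 and 2 read 423 and 2900 for Adipoq, 1590 and 393 for Alb and 2260 and 712 for Ttr, and ganglia 3 and 4 read 53.6 and 190, 25.4 and 12.3, and 77.6 and 55.3.

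The ganglion and tumor contrasts share the wild-type arrays. Across the 15132 genes, which are not independent replicates, their log2 fold changes correlated with r = 0.722 and a covariance of 0.419. Unchanged groups simulated against shared controls gave a mean r of 0.408 and a mean covariance of 0.0319 over 100 draws. The simulated arrays varied independently, with 1 spread per gene and without the split of the wild-type ganglia. These simulated values may therefore be too low as a reference. The measured covariance was 0.336 with wild-type ganglia 1 and 2 for the ganglion contrast and 3 and 4 for the tumor contrast, and 0.177 the other way round. In both contrasts 598 genes rose and 150 fell, where independent lists would share 140 and 41, and 1 gene went opposite ways. With separate controls, r was 0.618 when the ganglion contrast used wild-type ganglia 1 and 2, where 443 genes rose and 32 fell in both (123 and 13.2 for independent lists) and 5 went opposite ways. It was 0.195 when that contrast used 3 and 4, where 1149 rose and 786 fell in both (634 and 652 for independent lists) and 1091 went opposite ways.

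Tumors with Mdk knockout were set against homozygous tumors to see what the loss of midkine changes. Only Mdk itself passed: 39 ± 5 (SD, n = 2) against 277 ± 13.9 (SD, n = 4), a log2 fold change of -2.41 (SE 0.29, adjusted p = 0.0017). Mdk no longer passed without knockout tumor 1 (log2 -2.51, adjusted p = 0.068) or without knockout tumor 2 (-2.32, adjusted p = 0.18), and its adjusted p was between 1.6e-06 and 0.18 over the settings fixed beforehand. The antigen presentation and macrophage lists passed upward at the preset correlation without any member passing alone (adjusted p = 0.53 and 0.97 with an estimated correlation). Both were lost without knockout tumor 2 (adjusted p = 0.25 each). Iigp1, an interferon-induced GTPase, was 39 ± 3.65 against 16.1 ± 3.53, and H2-Aa, a class II chain, 495 ± 28.6 against 222 ± 44.5, neither of which passed (adjusted p = 1).

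Of 15132 genes 1 passed and 200 had an unadjusted p under 0.05. These were 1.32% of the genes, whereas a share of about 0.05 would fall there without any effect. The p-values of this contrast may therefore be too high. The lack of further passing genes does not show that nothing else changed. The genes nearest to passing were Ccdc180 (log2 -1.64, adjusted p = 0.52), Narf (-1.03) and Hoxa5 (-0.87) on the lower side and Cort (0.71), Rtp4 (1.23) and H2-Aa (1.12) on the higher side. The antigen presentation list had an adjusted p of 4.3e-07 (median 0.38), and 0.53 with an estimated correlation; the macrophage list 0.003 (median 0.27), and 0.97 with an estimated correlation. The skeletal muscle list had 0.023, and an adjusted p of 0.97 with an estimated correlation, with Acta1 at 27.8 and 1050 on the knockout arrays. Cell cycle (median 0.02), sympathetic (0) and neuron (-0.2) lists did not pass. By the probe sets used, Mycn, Alk, Ptprz1, Notch2 and Hes1 were within 0.22 of no change and did not pass, while the second Mycn probe set was at 0.38 and another Notch2 probe set at -0.23. Without the 6 arrays with Acta1 over 100, which leaves 1 knockout tumor, Mdk did not pass, Nrip2 rose (3.09, adjusted p = 0.016) and the antigen presentation list was lost too (adjusted p = 0.23). Ccdc180 passed when only the compared arrays were fitted (-1.64, adjusted p = 0.018) or with array weights (-1.66), and Gldc, of glycine breakdown, without homozygous tumor 2 (2.03). Nrip2 and Gldc lie outside the rule for named genes and were named after their values were seen.

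Hemizygous tumorspheres were set against wild-type neurospheres, the only wild-type sphere cultures here. The cultures differed in lineage genes. In the sympathetic noradrenergic list 18 of 22 rose and none fell, with Th, which makes catecholamines, at 3210 ± 163 (SD, n = 2) against 11.9 ± 3.11 (SD, n = 2), and Hand2, a sympathetic transcription factor, at 1270 ± 81.5 against 6.88 ± 1.62. In the neural crest and neural stem list 15 of 26 fell and 1 rose, with Sox2, a stem cell transcription factor, at 2.97 ± 2.61 against 3540 ± 344 and Olig1, of the oligodendrocyte lineage, at 2.93 ± 1.04 against 3550 ± 16.7. In the Notch list 15 of 28 fell and 5 rose, with Hes5 at 13.8 ± 2.48 against 1560 ± 1190. The tissue from which the neurospheres were grown is not in the labels. Both neurosphere arrays read transcripts of both sexes, with Xist at 1690 and 1650 and the Y-linked Eif2s3y at 722 and 541. The sex term set them to 0.5, between female and male. The beta-actin 3' to 5' ratio averaged 2.49 in tumorspheres and 5.78 in neurospheres, and the GAPDH ratio 2.9 and 7.44. RNA quality therefore cannot be separated from the kind of culture.

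Of 15132 genes 5808 changed, 3552 higher and 2256 lower. The highest were Th (log2 6.86), Ddc (6.81), Isl1 (6.81), Agtr2 (6.8), Tfap2b (6.8) and Hand2 (5.82), and the lowest Fabp7 (-8.36), Ptprz1 (-7.72), Olig1 (-7.56), Sox2 (-7.55), Rgs20 (-7.23) and Gja1 (-7.16). The sympathetic (adjusted p = 7e-11), neural crest and stem (9.7e-11), neuron (4.6e-09, 21 of 27 rose and 1 fell) and Notch (0.00051) lists also passed with an estimated correlation, with an adjusted p of 0.022, 0.006, 0.022 and 0.009. In the cell cycle list 24 of 39 rose, and 30 adjusted over the list alone (adjusted p = 1.1e-06, and 0.4 with an estimated correlation) and in ribosome biogenesis 22 of 42 rose and 1 fell (0.00078, and an adjusted p of 0.64 with an estimated correlation). The ribosome list was lost without neurosphere 1 (adjusted p = 0.19). In the glycolysis list 12 of 26 fell and 4 rose (0.0057, and an adjusted p of 0.16 with an estimated correlation), in the glial list 9 of 19 fell and 2 rose (0.012 and 0.34) and in the fibroblast list 6 of 29 fell and 3 rose (0.028 and 0.79). The Mbp probe set used, for a myelin protein, rose by 3.02, but of 7 others 6 were at -0.26 to -1.32 and 1 at 1.26. Mdk rose by 2.82 (SE 0.33) and Alk by 4.24 (SE 0.33), and Notch2 and Hes1 fell by 3.26 and 2.07, where the neurospheres read 2420 and 484 for Notch2 and 27.3 and 220 for Hes1. Hes1 was at -0.85 without neurosphere 2 (adjusted p = 0.18), and passed neither without tumorsphere 2 (adjusted p = 0.062) nor when only the compared arrays were fitted (adjusted p = 0.1). Notch2 still passed without neurosphere 1 (adjusted p = 0.04) and was at -1.51 as the mean of its probe sets.

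Hemizygous and homozygous tumors were compared to see whether transgene dose went with differences between tumors. In the endothelium list 13 of 20 rose and none fell, and 17 rose adjusted over the list alone, with Kdr, a VEGF receptor, at 163 ± 46.4 (SD, n = 4) against 53.5 ± 9.05 (SD, n = 4), and in the macrophage list 6 of 21 rose, with Cd68 at 281 ± 117 against 117 ± 27.4 (adjusted p = 0.11 and 0.29 with an estimated correlation). The macrophage mean of hemizygous tumor 3, 6.74, lay within the 6.7 to 6.97 of homozygous tumors. Rgs5, of pericytes, was 1370 ± 290 against 479 ± 52.2. In the sympathetic list 4 of 22 fell and 1 rose, and in the neuron list 6 of 27 fell and 1 rose (adjusted p = 0.29 and 0.14 with an estimated correlation). Slc6a2 was 136 ± 202 against 922 ± 281, and Mapt, which encodes tau, 43.6 ± 11.9 against 144 ± 25.9.

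Of 15132 genes 939 changed, 524 higher and 415 lower. The split depended on the scaling, with 410 higher and 457 lower after median centring, 486 and 490 after quantile normalization and 277 and 280 with a pseudocount of 1, and it was 202 and 215 with a 2-fold threshold added. Asb4, St18, Nptx2, Ak5, Calb2 and Clec4a3 were the highest (log2 3.33 to 2.58), and Egln3, Slc6a2, Fabp7, Pclo, Kcnd2 and Sorcs1 the lowest (log2 -4.66 to -2.78). The endothelium list had an adjusted p of 1.6e-13 (median 0.99), and 0.11 with an estimated correlation. Macrophage (4.7e-06), smooth muscle and pericyte (0.00067, 3 of 13 rose), antigen presentation (1.3e-06, 4 of 22 rose), ribosome biogenesis (2.4e-07, 6 of 42 rose, 15 adjusted over the list alone) and immediate early (0.034) lists also went up, each with an adjusted p of 0.29 with an estimated correlation. Neuron (1.8e-06, 6 of 27 fell and 1 rose, or 12 and 2 adjusted over the list alone), sympathetic (0.00092, 4 of 22 fell), sterol (0.0089) and glial (0.029) lists went down, with an adjusted p of 0.14, 0.29, 0.29 and 0.34 with an estimated correlation. In the sympathetic list Chgb rose by 1.89. Mdk did not pass (log2 0.23, adjusted p = 0.66), and Mycn by its brighter probe set (-1.67), Alk (-0.94) and Ptprz1 (-1.28) fell, Alk not without homozygous tumor 1 (-0.86, adjusted p = 0.081) and Mycn not as the mean of its probe sets (-0.44, adjusted p = 0.17). The count was 446 without homozygous tumor 1 (216 higher, 230 lower), 498 without 2, 494 without 3 and 468 without hemizygous tumor 4, and 1966 when only these 8 arrays were fitted. Acta1 was over 100 in 1 tumor of each group, and the skeletal muscle list did not pass (adjusted p = 0.45).

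**Figure D3:**
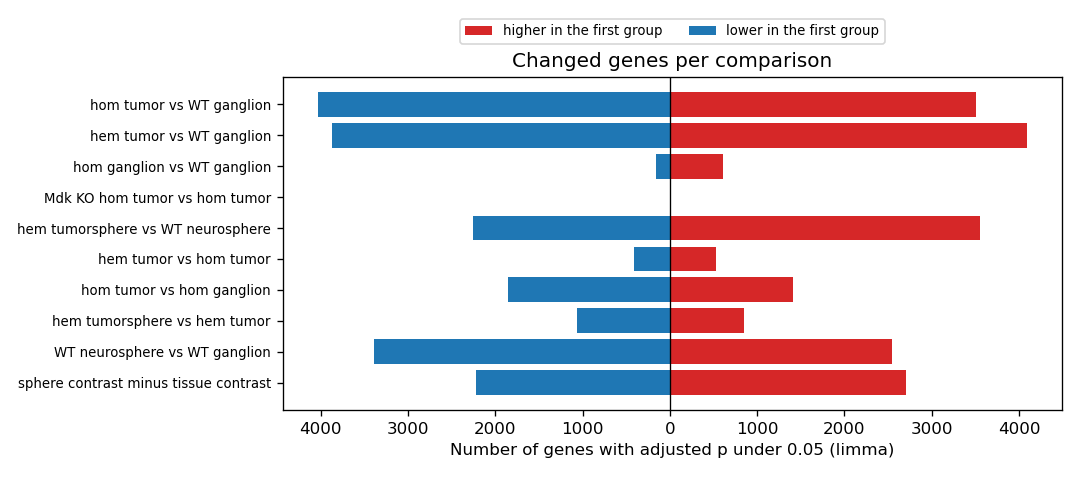
Number of genes per comparison with a limma adjusted p under 0.05, higher (right) and lower (left) in the first group named. Tumors against wild-type ganglia show the most, 7533 and 7958, and the Mdk knockout comparison 1.

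The 4 further comparisons place the groups against each other. Homozygous tumors against homozygous ganglia changed 3271 genes (1415 higher, 1856 lower), or 6291 when only the compared arrays were fitted and 7065 with array weights. Dlk1 rose by 2.8 and Cd5l, a macrophage protein, by 4.08, while Npy fell by 4.92 and Fabp7 by 3.58. Cell cycle genes rose further in 20 of 39 (median 0.81), and fibroblast genes fell in 19 of 29 and rose in 1 (adjusted p = 7.1e-11 and 3.5e-09, and 0.25 for both with an estimated correlation). The count was 1468 without homozygous ganglion 1 and 841 without 2. Tumorspheres against hemizygous tumors changed 1907 genes (849 higher, 1058 lower). In the tumorspheres 20 of 21 macrophage, 18 of 20 endothelium and 21 of 29 fibroblast genes fell and 2 fibroblast genes rose, each list also with an estimated correlation (adjusted p = 0.013, 0.013 and 0.037 with an estimated correlation). The smooth muscle list (8 of 13 fell) and the Notch list (6 of 28 fell, 2 rose) also passed with it (0.039 and 0.013), and the lymphocyte list (2 of 13 fell) did not pass (adjusted p = 0.092). Lyz1, a lysozyme, was 3.23 ± 4.08 (SD, n = 2) against 3080 ± 509 (SD, n = 4), and Chac1, a gene of the integrated stress response, and Vgf were the highest (3.37 and 3.28). The brighter Mycn probe set rose by 3.23. The count was 709 without tumorsphere 1 and 742 without 2. Centring each array on its median turned the split to 1132 higher and 828 lower, with a median of all genes of 0.12. Neurospheres against wild-type ganglia changed 5934 genes (2540 higher, 3394 lower, or 2872 and 2825 after median centring), with Slc1a3, a glutamate transporter of glia, at 2260 ± 122 against 6.49 ± 6.3 and Ddc, of catecholamine synthesis, at 10.4 ± 0.308 against 6450 ± 2500. In the sympathetic list 20 of 22 fell and 1 rose, and in the neuron list 24 of 27 fell and 1 rose (adjusted p = 0.017 and 0.0074 with an estimated correlation). The sphere contrast differed from the tissue contrast for 4924 genes (2701 higher, 2223 lower), led by Th, Ret, Npy and Ddc, with differences of 9.11, 9.05, 7.97 and 7.77. The tumorsphere and hemizygous tumor contrasts share no arrays, and their log2 fold changes correlated across genes with r = 0.362.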

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

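The tests of other tissue in wild-type ganglia, of the choice of ganglia, of the tumor cell share and of sex for the macrophage list, and the comparison of the probe set correlation with other groups, were chosen only after the result was seen. With the group labels exchanged among the 8 arrays, 1 of 35 splits (the real one) gave as many changed genes in each comparison of groups of 4: 7533 against at most 129 for homozygous tumors and wild-type ganglia, 7958 against at most 435 for hemizygous tumors, and 939 against at most 30 for the 2 tumor groups. This argues against chance assignment but does not exclude it, as 1 of 35 is the smallest share the splits allow. Splits that mix the groups also widen the spread within groups, which lowers their counts. Other properties that go along with the groups are not addressed by the splits.

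Single arrays stood apart from the other 3 of their group in 7 of the 99 sets of values examined, or 7.1%, where chance gives about 1 in 20. The skeletal muscle list mean was 6.44 in homozygous tumor 2 (others 4.55 to 4.67) and 8.94 in hemizygous tumor 3 (others 4.58 to 4.68). In homozygous tumor 4 the erythroid list mean was 4.39 (others 4.61 to 4.63), in homozygous tumor 2 the actin ratio was 2.81 (others 2.44 to 2.48), and in homozygous tumor 1 Mdk was 297 (others 268 to 271). The neuron list mean was 7.78 in hemizygous tumor 1 (others 7.86 to 7.88), and the smooth muscle list mean 7.44 in hemizygous tumor 4 (others 6.83 to 6.9).

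The sphere and tissue contrasts differed by the model's interaction contrast for 4924 genes. The list medians of the difference were 4.53 for sympathetic noradrenergic genes, 4.68 for neuron genes, -1.6 for neural crest and stem genes and -0.97 for Notch genes. In neurospheres against wild-type ganglia the sympathetic and neuron medians were -3.81 and -3.67, and in tumorspheres against hemizygous tumors 0.15 and 0.66. The larger part of the sympathetic and neuron differences therefore lay between neurospheres and wild-type ganglia. The second Mycn probe set, which the comparisons did not use, averaged 31.1 in homozygous ganglia, 44.5 in homozygous tumors, 55.2 in hemizygous tumors and 94.1 in tumorspheres, above the highest of the wild-type arrays, 14.9.

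Wild-type ganglia 1 and 2 stood apart from 3 and 4, and 2723 of 15132 genes were at least 2-fold apart without overlap (1658 higher in 1 and 2, 1065 higher in 3 and 4). With 2 arrays against 2, 33.3% of genes would not overlap by chance, so the lack of overlap alone adds little. Of the 2723, 39.1% were higher in 3 and 4, against other tissue dissected with ganglia 1 and 2 as the whole cause. The medians of ganglia 3 and 4 minus 1 and 2 were -3.64 for skeletal muscle, -2.16 for adipocyte, 0.31 for sympathetic and 0.08 for neuron genes. Alb, at 1590 and 393 in ganglia 1 and 2, read 25.4 and 12.3 in 3 and 4. Ttr read 2260 and 712 against 77.6 and 55.3. These values leave added muscle, fat or other tissue, and some dilution of the other genes, open as a part. The male minus female difference of homozygous tumors correlated with the gap by r = 0.0465 across genes. This cannot decide on sex, because the difference came from 2 male and 2 female arrays of another tissue. Ganglia 1 and 2 read as female and 3 and 4 as male, so sex cannot be separated from the gap. No biological explanation besides sex and added tissue was examined. A preparation effect shared with wild-type neurosphere 1 is a candidate explanation: differences between 2 probe sets of the same gene moved together, r = 0.433 across 3547 genes, though replicates 3 and 4 minus 1 and 2 of homozygous tumors gave 0.26 and those of hemizygous tumors -0.211. The highest intensity on an array was 17948.5 and 12634.9 in wild-type ganglia 3 and 4 and 13238 in neurosphere 1. On all other arrays, the tumors among them, it was 5112.93 to 6997.15.

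The cell cycle list was higher in homozygous ganglia. Against wild-type ganglia 1 and 2 alone its median was still 1.95, against the choice of controls as the cause. A share of tumor tissue in these ganglia may contribute: the median share of the difference between tumors and wild-type ganglia that was reached, on the linear scale, was 47.8% for cell cycle genes, 35.7% for other genes 4-fold higher in tumors and 49.3% for genes 4-fold lower, and the first 2 gave a gap of 12.1 percentage points, which lies between the bounds set beforehand, so an admixture and more division among the ganglion cells themselves cannot be told apart.

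The endothelium and macrophage medians were 0.99 and 0.67 in hemizygous against homozygous tumors (adjusted p = 0.11 and 0.29 with an estimated correlation), and the macrophage mean of hemizygous tumor 3, 6.74, lay within the homozygous 6.7 to 6.97. A lower share of tumor cells would raise every other cell type alike only if the other cells had the same make-up in both groups. Tumor cells would also have to lack the listed genes, and Fabp7 of the glial list was among the lowest genes of this comparison. The endothelium median exceeded that of the glial list by 1.18, with endothelium minus glia at 0.13 to 0.72 on hemizygous and -0.99 to -0.77 on homozygous arrays. This argues only against an equal rise of all other cell types. A lower share of tumor cells stays open, with smooth muscle at 0.79, skeletal muscle 0.64, fibroblast 0.38, adipocyte 0.24, lymphocyte 0.18, erythroid 0.08, adrenal cortex 0 and glia -0.19. Among male arrays alone the endothelium median was 0.86, against sex as the cause for that list, while the macrophage median was 0.49, between the bounds, so sex stays open there. An effect of transgene dose may be among the open explanations, together with tumor age and site, which were not tested.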

How the results depend on the processing

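A change of direction was counted only where the main or the alternative value passed. Quantile normalization, median centring, a pseudocount of 64, no filter, the 60th percentile filter, the mean of probe sets, leaving out the _x_at and _s_at probe sets, the variance trend, the term for replicates 1 and 2 against 3 and 4 and the sex term (chosen after seeing the data) left the counts they were run on within 1.5 times. The array weights stopped before their tolerance was reached. Adding a 2-fold threshold left 3910, 4474, 417, 1813, 1189 and 3836 genes for homozygous and hemizygous tumors against wild-type ganglia, hemizygous against homozygous tumors, homozygous tumors against homozygous ganglia, tumorspheres against tumors and neurospheres against ganglia. Array weights gave 2, 2637, 7065, 5124 and 3311 for the Mdk knockout, hemizygous against homozygous tumors, homozygous tumors against homozygous ganglia, tumorspheres against tumors and neurospheres against ganglia; fitting only the compared arrays gave 144 for homozygous ganglia, 2 for the Mdk knockout, and 1966, 6291 and 2813 for hemizygous against homozygous tumors, homozygous tumors against homozygous ganglia and neurospheres against ganglia. A pseudocount of 1 gave 557 for hemizygous against homozygous tumors. Splits turned as well. Median centring gave 1132 higher and 828 lower for tumorspheres against tumors (849 and 1058 before), 410 and 457 for hemizygous against homozygous tumors (524 and 415) and 2872 and 2825 for neurospheres against ganglia (2540 and 3394). Quantile normalization gave 3802 and 4036 for hemizygous tumors against wild-type ganglia (4086 and 3872) and 486 and 490 for the 2 tumor groups, which a pseudocount of 1 (277 and 280), the 2-fold threshold (202 and 215) and leaving out homozygous tumor 1, 2 or 3 or hemizygous tumor 4 turned too. The 60th percentile filter gave 3437 and 3427 for homozygous tumors against wild-type ganglia (3503 and 4030), and array weights (2663 and 2461) and a pseudocount of 64 (955 and 954) turned tumorspheres against tumors. Chosen after seeing the data, wild-type ganglia 1 and 2 alone gave 3835 and 3944 for hemizygous tumors.

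The replicate number as a block is not a pairing here: the best match was the own number in 5 of 24 cases among the groups of 4. The block gave 434 genes for homozygous ganglia and moved no other count by over 1.5 times.

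Chosen after seeing the data, wild-type ganglia 3 and 4 alone gave 5283 genes for homozygous ganglia, and leaving out the arrays with high Acta1 gave 3079 there and 1869 for homozygous tumors against homozygous ganglia. The overlap of ganglion and tumor contrasts moved from r = 0.722 to 0.618 and 0.195 with split controls.

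With 1 array left out, the counts ran from 6679 to 7667 and 7311 to 8137 for homozygous and hemizygous tumors against wild-type ganglia, 189 to 2232 for homozygous ganglia, 0 to 2 for the Mdk knockout, 4123 to 5847 for tumorspheres against neurospheres, 446 to 945 for hemizygous against homozygous tumors, 841 to 2962 for homozygous tumors against homozygous ganglia, 709 to 2028 for tumorspheres against tumors, 4438 to 6208 for neurospheres against ganglia and 3654 to 5345 for the interaction. A group left with 1 array is assumed to vary like the others.

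Directions changed for Mbp in tumorspheres against neurospheres (-0.68 with a pseudocount of 64, -0.12 with the mean of probe sets, -1.32 without the _x_at and _s_at probe sets) and, without these probe sets, for Hbb-b2 in homozygous tumors against homozygous ganglia (0.38), Cbx6 in tumorspheres against tumors (0.03) and Ppat in the interaction (1.28). The skeletal muscle list reversed in homozygous ganglia when 1 array was left out, from -1.83 without homozygous ganglion 2 to 1.7 without homozygous ganglion 1, and in the Mdk knockout from -0.38 without knockout tumor 2 to 2.16 without knockout tumor 1. Without the arrays with high Acta1 (chosen after seeing the data) the direction of its test turned down there, with the median still above 0 (0.02, adjusted p = 0.81). The 60th percentile filter gave 210 of 230 list results. With an estimated correlation 83 of 99 list calls were lost. The cause was not tested for any of the values in this part. Unequal spread of the groups stays open for the counts with only the compared arrays. Low intensity limits small values: 40.4% to 51.3% of probe sets on an array lay under the pseudocount.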

Other observations

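In the p53 target list 10 of 18 rose and 2 fell in neurospheres against wild-type ganglia (median 0.89, adjusted p = 0.0028, and 0.22 with an estimated correlation), and 3 of 18 rose in tumorspheres against hemizygous tumors (median 0.36, adjusted p = 0.023, and 0.31 with an estimated correlation), but this was lost without tumorsphere 2 (median 0.08, adjusted p = 0.21). In the sterol biosynthesis list 6 of 19 rose in tumorspheres against hemizygous tumors (median 0.54, adjusted p = 0.0012, and 0.14 with an estimated correlation), while in neurospheres against ganglia the list did not pass (median -0.47, adjusted p = 0.29).

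Probe sets without a single gene symbol were tested apart with limma. Of 6684 that passed the filter, 2819 changed between homozygous tumors and wild-type ganglia, 1952 higher and 867 lower. The 2 tumor contrasts against wild-type ganglia shared 3058 named genes that rose and 3186 that fell, with r = 0.922. Unchanged groups simulated against shared controls gave a mean r of 0.501, which may be too low because the simulation lacked the split of the wild-type ganglia. With wild-type ganglia 1 and 2 for homozygous and 3 and 4 for hemizygous tumors r was 0.643, and 0.734 the other way round. In the first of these settings the 2 contrasts shared 2322 and 2236, where independent lists would share 1000 and 1150, and 514 went opposite ways. The other way round they shared 2625 and 2484, where independent lists would share 1010 and 1150, and 270 went opposite ways.

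Knockout alleles can carry along strain variants of the surrounding chromosome, which might change neighbouring genes. The 40 tested genes nearest to Mdk on its chromosome were taken by start position in assembly GRCm38.p6. Of these, 0 had an unadjusted p under 0.05 in the limma knockout comparison, against 1.32% of all genes, so no such change was detected. At that rate hardly any of 40 genes would be under 0.05, so smaller changes of neighbours are not excluded. The rate is itself below the share of 0.05 that unchanged genes would give, so these p-values may be too high.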
